A study of Mus musculus with 9 samples.

How the data were processed

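RNA was measured by sequencing of polyadenylated RNA in 9 libraries of 4T1 cells, 3 per group, prepared with the QIAseq FX Single Cell RNA Library Kit and read on an Illumina HiSeq2000, per the labels' protocols. Replicates were grouped as their titles give them. The submitters' processing notes name the mm10 build, Bowtie 0.12.9, Cufflinks 2.1.1 and HTSeq without a version; whether the counting used strand is not given in the sources used here.

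The deposited table gives read counts per gene and library, which the authors did not normalize further, per the file headers. It also gives FPKM, which the authors made by dividing the counts by gene length and library size, per the file headers. These deposited FPKM equal the count divided by gene length and library total, times a factor per library that lay between 0.875 and 1.238 and whose origin is not given in the sources used here. For each comparison the authors also deposited means per group, per the file headers, which were not used here. The authors also deposited log2 fold changes, per the file headers. The deposited p-value columns, raw and adjusted, come from a test by the authors that is not given in the sources used here. Total counts lay between 15477324 and 17494776 per library. Of the gene identifiers, 54409 are also in GENCODE M21, and 98.3% of these have the same coordinates there.

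Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr, a robust quasi-likelihood fit of all 9 libraries with a mean per group, and Benjamini-Hochberg adjustment over the 13915 genes tested. Genes with an adjusted p under 0.05 are called. The common dispersion was 0.0112, a biological coefficient of variation of 10.6%. CPM are scaled by the TMM factors, and standard errors of log2 fold changes were taken as the absolute value divided by the square root of F. Gene lists were tested with camera of limma 3.58.1 with a correlation preset to 0.01, adjusted over 93 tests, and again with an estimated correlation. Lists with fewer than 5 genes tested got no test. The 5 lists added after seeing the data were adjusted over 15 tests of their own. The design, the 35 lists, the alternatives and the rule for named genes were written before the data were examined.

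The rule takes 3 sets per comparison. The first holds the 8 risen and 8 fallen genes with the largest absolute log2 fold change among called genes with at least 5 CPM in the higher group, no overlap between the libraries of the groups, and a symbol that is not a predicted gene, a Rik clone or a pseudogene. Another holds, for each list, the 4 called members with the smallest p or, with none, the member with the highest mean CPM. The last holds Mt1, Mt2, Hmox1, Slc7a11, Gclm, Gpx4, Txnip, Hspa1a, Ddit3 and Cdkn1a. The rule gave 135, 143 and 139 genes for the 3 comparisons, and the examples printed were picked from these after their values were seen, while the sensitivity counts cover the whole set. Levels of a gene are printed in any group beside a comparison that names it.

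Alternatives were RLE factors, library totals alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, the 6 libraries of a comparison alone, a replicate block, a log2 fold change of at least 1, limma on log2 FPKM with pseudocounts of 1 and 0.1, and leaving out each library. Offsets for the trend of counts on gene length, with and without GC content (splines with 5 degrees of freedom), protein-coding genes alone, leaving out the most counted genes, list tests with library totals alone, and counts of genes called with both materials without 1 Cu_TCPP or Au_TCPP library were added after seeing the data. The fit was tested on simulated data for 13915 genes with 100 genes changed per fold size. For Cu_TCPP against Control, 84% of 2-fold and 62% of 1.5-fold changes were recovered, with 12 false among 158 calls. For Au_TCPP against Control these were 84% and 64%, with 9 false among 157 calls, and for Au_TCPP against Cu_TCPP 82% and 68%, with 5 false among 155. The simulated changes were few, raised and lowered in equal number, with the same spread in all groups. They do not test the scaling or the error rate where, as in Au_TCPP against Control, 9611 genes are called, or where groups differ in spread. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.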

Results

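RNA was sequenced from 9 libraries of 4T1 cells, a mouse mammary carcinoma line used as a model of triple-negative breast cancer. The cells received medium alone (Control), Cu-TCPP(Fe)-PEG (Cu_TCPP) or Au/Cu-TCPP(Fe)-PEG (Au_TCPP), with 3 libraries per group, and the treatments lasted 24 h. The labels describe the copper material as consuming glutathione (GSH) and the material with gold as consuming GSH and, in addition, acting as a glucose-like oxidase; doses were not given in the sources used here. Total counts were 16108691, 16638173 and 16429404 in Control, 16225399, 17494776 and 16595300 in Cu_TCPP and 16404074, 15477324 and 16002188 in Au_TCPP. The deposited table lists 54532 genes, of which 13915 had enough counts to be tested. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which can be technical. Gene levels below are CPM, read counts scaled to the effective library total, as mean ± SD with n = 3, and adjusted p-values of genes are from edgeR's quasi-likelihood test. Genes were grouped by 31 lists with enough genes tested, each given with the number that rose, fell or did not pass, the median log2 fold change and the adjusted p of limma's camera over 93 tests. camera called 58 of the 93 with its preset correlation and 0 with an estimated correlation, where 19 had an unadjusted p under 0.05. Some lists share genes, so their results are not independent. The NRF2 and glutathione lists share 7 genes, the NRF2 and pentose phosphate lists 4, and the p53 and apoptosis lists 4.

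The Au_TCPP libraries lay apart from the other two groups on the first principal component (64.3% of the variance of log2 CPM), and the Cu_TCPP libraries lay apart from Control on the second (19.6%). Ribosomal protein genes took 10.2% ± 0.467 of the counts in Au_TCPP (SD, n = 3), against 6.16% ± 0.175 in Control and 5.82% ± 0.134 in Cu_TCPP. The mean length of the counted gene was 4607 ± 60.1 nt in Au_TCPP, 5688 ± 61.6 nt in Control and 5650 ± 62.2 nt in Cu_TCPP (SD, n = 3). Across the genes tested, which are not independent replicates, the log2 fold change of Au_TCPP against Control fell with exonic length, with a Spearman correlation of -0.30 against -0.00785 for Cu_TCPP. Genes of up to 500 nt had a median of 0.86 with Au_TCPP and genes over 8000 nt a median of -0.45. In Au_TCPP replicate 2, 2.37% of the counts came from mitochondrially encoded genes (Wilson 95% interval 2.359 to 2.374%, which covers counting error only), against 1.09 to 1.47% in the other 8 libraries. With library totals as the only scale, the median of all genes tested lay at -0.43 for Au_TCPP against Control and -0.33 for Au_TCPP against Cu_TCPP. The fold changes below are relative to that shift, as they use TMM factors. The medians of the lists relative to the median of all genes moved by at most 0.03 between the scales. That is so by construction, since a scale factor moves all genes of a library alike. With library totals the medians themselves changed sign in 10 of the 35 lists, 1 of them called, for Au_TCPP against Control. For Au_TCPP against Cu_TCPP they did so in 3, 1 of them called.

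**Figure D1:**
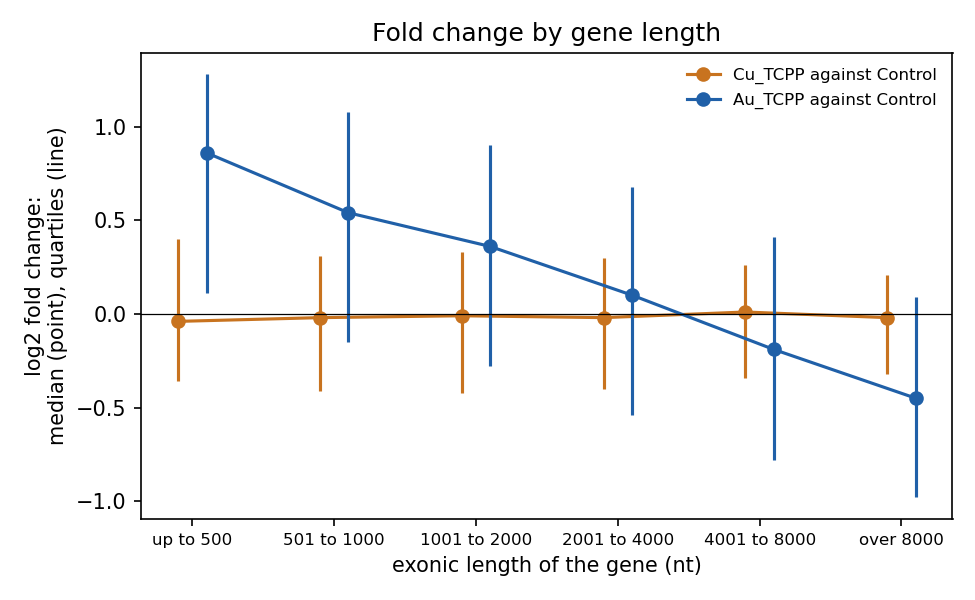
Median log2 fold change against Control (points, with lower and upper quartiles as bars) of the genes tested in 6 classes of exonic length in nt, for Cu_TCPP and Au_TCPP. The Au_TCPP medians go from 0.86 in genes of up to 500 nt to -0.45 in genes over 8000 nt, while the Cu_TCPP medians stay between -0.04 and 0.01.

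The comparison of Cu_TCPP with Control addresses what the GSH-consuming copper material changed in the cells. In the interferon-response, chemokine and matrix lists 28 of 30, 19 of 30 and 13 of 22 genes fell with Cu_TCPP, and 24 of 28 ribosome biogenesis and 15 of 21 heat shock genes rose. These 5 calls were lost with an estimated correlation (adjusted p = 0.23, 0.067, 0.23, 0.089 and 0.38 with an estimated correlation). The metallothionein gene Mt1, whose product binds copper and zinc, rose 3.42-fold, from 98.1 ± 4.45 to 335 ± 37.5 CPM. Txnip, whose product binds thioredoxin and limits glucose uptake, fell 7.89-fold, from 382 ± 25.9 to 48.4 ± 3.86 CPM. Of the 13915 genes tested, edgeR called 2673 higher and 2944 lower, and 217 of the higher and 929 of the lower genes changed by at least 1 log2 unit. The fit shares 1 spread per gene over all 9 libraries, so the Au_TCPP libraries enter these p-values. The total of 5617 was 7179 without Au_TCPP replicate 2 and 7381 in a fit of these 6 libraries.

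Among genes of metal handling, Mt1 (ENSMUSG00000031765, mm10 chromosome 8, 94179082 to 94180327) had a log2 fold change of 1.77 (adjusted p = 1.2e-05). Mt2 rose from 1.52 ± 0.212 to 5.2 ± 1.3 CPM, and Slc30a1, a zinc exporter, rose 3.2-fold. Slc31a2, a copper transporter, fell 1.92-fold. In the copper and metallothionein list, 5 of 19 genes rose, 3 fell and 11 did not pass; the list as a whole was not called (camera adjusted p = 0.19). For cuproptosis and protein lipoylation, 5 of 14 genes rose, 0 fell and 9 did not pass (median 0.23, camera adjusted p = 0.0068, and adjusted p = 0.14 with an estimated correlation). Its risen members include Fdx1, the ferredoxin that serves lipoylation, at 30.1 ± 1.61 against 18.7 ± 0.602 CPM, and Gcsh, the lipoylated protein of the glycine cleavage system, at 105 ± 6.18 against 55.2 ± 0.249 CPM. For iron handling and ferroptosis, 6 of 23 genes rose, 7 fell and 10 did not pass, with a median of 0.05, a mean of -0.06 and no call (camera adjusted p = 0.98). Gpx4, the peroxidase that removes lipid hydroperoxides, fell from 531 ± 19.3 to 295 ± 16.1 CPM.

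In the list of targets of NRF2, the transcription factor of the oxidative stress response, 13 of 29 genes rose, 5 fell and 11 did not pass, and the list was not called (camera adjusted p = 0.073). It passed without Au_TCPP replicate 2 (0.02), Au_TCPP replicate 3 (0.034) or Cu_TCPP replicate 1 (0.041), and with library totals alone (0.036). Hmox1, which encodes heme oxygenase 1, rose 3.39-fold from 15.2 ± 1.59 to 51.4 ± 3.14 CPM, and Gclm, the modifier subunit of the first enzyme of GSH synthesis, rose 2.13-fold to 338 ± 12.4 CPM. Aldh3a1, an aldehyde dehydrogenase, fell 7.96-fold from 33.1 ± 4.25 to 4.14 ± 0.475 CPM, and Ephx1, an epoxide hydrolase, fell 4.03-fold. In glutathione metabolism, 4 of 25 genes rose, 9 fell and 12 did not pass, with no call (camera adjusted p = 0.055, 0.036 without Control replicate 1 and 0.047 with offsets for length and GC content). Mgst1, a microsomal glutathione transferase, fell from 41.4 ± 1.98 to 18.5 ± 2.13 CPM. Slc7a11, the cystine importer, stood at 42.2 ± 3.58 against 35.8 ± 1.48 CPM and did not pass (adjusted p = 0.73), although a fit of these 6 libraries alone gave 0.014. The fit of all 9 libraries shares 1 spread per gene, and Slc7a11 stood at 137, 46.7 and 211 CPM in Au_TCPP replicates 1, 2 and 3.

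In the heat shock list, 15 of 21 genes rose, 0 fell and 6 did not pass (median 0.62, camera adjusted p = 4.1e-06, and adjusted p = 0.38 with an estimated correlation). Hsp90aa1, a cytosolic HSP90, rose from 946 ± 72.2 to 1934 ± 134 CPM and Hsph1, an HSP110 chaperone, from 63.9 ± 1.35 to 115 ± 4.41 CPM. In the unfolded protein response, 10 of 22 genes rose, 2 fell and 10 did not pass (median 0.24, camera adjusted p = 0.0032, and adjusted p = 0.44 with an estimated correlation), with Calr, a lectin chaperone of the endoplasmic reticulum, at 426 ± 6.69 against 242 ± 1.81 CPM. The ATF4 list was not called (camera adjusted p = 0.58) and had a median of 0.01 and a mean of -0.11: 6 of 27 genes rose, 6 fell and 15 did not pass. Ddit3, a transcription factor of the stress response also called CHOP, fell from 29.4 ± 1.88 to 10.6 ± 1.43 CPM, a value that is uncertain because Ddit3 overlaps Mars on the opposite strand and the use of strand in the counting is not stated. In ribosome biogenesis, 24 of 28 genes rose, 0 fell and 4 did not pass (median 0.77, camera adjusted p = 1.1e-18, and adjusted p = 0.089 with an estimated correlation). Nolc1, a nucleolar phosphoprotein, rose 2.46-fold to 249 ± 8.97 CPM and Rrs1, a ribosome assembly factor, 2.14-fold to 71.3 ± 5.41 CPM. Among ribosomal protein genes, which share reads with many pseudogenes and are uncertain one by one, 1 of 42 genes rose, 2 fell and 39 did not pass, and the list was not called (camera adjusted p = 0.98).

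For G1/S and DNA replication, 20 of 35 genes rose, 1 fell and 14 did not pass (median 0.34, camera adjusted p = 8.0e-05, and adjusted p = 0.35 with an estimated correlation). The replication licensing genes Cdc6 and Orc1 rose to 64.4 ± 3.23 from 38.4 ± 1.61 CPM and to 29 ± 1.49 from 17.3 ± 0.54 CPM. In DNA repair, 13 of 30 genes rose, 2 fell and 15 did not pass (median 0.22, camera adjusted p = 0.026, and adjusted p = 0.4 with an estimated correlation), with the exonuclease gene Exo1 at 45.4 ± 2.47 against 27.1 ± 1.22 CPM. The list of G2/M and mitosis was not called (camera adjusted p = 0.58): 5 of 34 genes rose, 4 fell and 25 did not pass. Of the p53 targets, 8 of 24 genes rose, 9 fell and 7 did not pass, with a median of 0.17, a mean of -0.04 and no call (camera adjusted p = 0.75). Cdkn1a, the cell cycle inhibitor p21, rose from 18.2 ± 0.923 to 32.5 ± 3.94 CPM and Aen, an apoptosis-enhancing nuclease, rose 3.9-fold, whereas Fas, a death receptor, fell 4.32-fold. Among apoptosis regulators, 5 of 27 genes rose, 10 fell and 12 did not pass (not called, camera adjusted p = 0.28). The genes of the BH3-only proteins Bcl2l11 and Bmf fell 1.98-fold and 5.99-fold.

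Txnip (ENSMUSG00000038393, mm10 chromosome 3, 96557957 to 96561883) leads the glucose-sensing list, in which 1 of 12 genes rose, 4 fell and 7 did not pass. That list had a median of -0.01 and a mean of -0.39 (camera adjusted p = 0.045, and adjusted p = 0.23 with an estimated correlation). Its median lay between -0.06 and 0.05 in the alternatives. The call ended with RLE factors (0.05), with offsets for gene length (0.054), and without Control replicate 1 or 3, any 1 Cu_TCPP library, or Au_TCPP replicate 2 or 3 (0.051 to 0.093). Arrdc4, an arrestin-like gene regulated with Txnip, fell from 9.17 ± 0.458 to 4.89 ± 0.265 CPM. Arrdc4 did not track Txnip with Au_TCPP, where Txnip was lower than in Control. There Arrdc4 stood at 16.3, 29.1 and 22.2 CPM in replicates 1, 2 and 3, against 9.56, 9.28 and 8.66 CPM in Control. In the hypoxia list, 8 of 22 genes rose, 2 fell and 12 did not pass (median 0.22, camera adjusted p = 0.018, and adjusted p = 0.54 with an estimated correlation), and Ak4, a mitochondrial adenylate kinase, rose from 43.2 ± 2.25 to 111 ± 2.31 CPM. Glycolysis genes went both ways and the list was not called (camera adjusted p = 0.98): 7 of 22 genes rose, 5 fell and 10 did not pass. Pfkfb3, which makes the activator of phosphofructokinase, fell 3.35-fold, and Eno1, an enolase, rose 1.57-fold. The lists of the pentose phosphate pathway (5 of 11 genes rose and 1 fell, camera adjusted p = 0.098), the TCA cycle (3 of 21 genes rose and 5 fell, camera adjusted p = 0.95), nuclear OXPHOS subunits (8 of 51 genes rose and 1 fell, camera adjusted p = 0.13), sterol biosynthesis (8 of 24 genes rose and 1 fell, camera adjusted p = 0.078) and fatty acid synthesis (3 of 18 genes rose and 2 fell, camera adjusted p = 0.22) were not called. The OXPHOS list passed without Cu_TCPP replicate 1 (0.039), and the sterol list without Control replicate 3 (0.043) or Au_TCPP replicate 2 (0.0015), with a replicate block (0.037) and with library totals alone (0.046). None of the 12 mitochondrially encoded genes passed (camera adjusted p = 0.93, median 0.03, mean -0.07). Fasn, the fatty acid synthase, rose from 458 ± 19.9 to 754 ± 32.8 CPM.

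In the interferon-response list, 0 of 30 genes rose, 28 fell and 2 did not pass (median -2.16, camera adjusted p = 8.1e-15, and adjusted p = 0.23 with an estimated correlation). Oas2, an antiviral oligoadenylate synthetase, fell 22.2-fold to 0.24 ± 0.143 CPM, and Ifit1, an antiviral RNA-binding protein, fell 4.37-fold to 0.91 ± 0.484 CPM. Among chemokines and NF-kB targets, 1 of 30 genes rose, 19 fell and 10 did not pass (median -0.54, camera adjusted p = 1.1e-07, and adjusted p = 0.067 with an estimated correlation), with Cx3cl1 at 39 ± 2.66 against 142 ± 8.39 CPM and Ccl20 at 1.11 ± 0.286 against 20 ± 1.73 CPM. Of the genes of MHC class I presentation, 1 of 17 genes rose, 10 fell and 6 did not pass (median -0.73, camera adjusted p = 0.0022, and adjusted p = 0.44 with an estimated correlation). Nlrc5, the transactivator of these genes, fell 1.99-fold. Nlrc5 did not track the list with Au_TCPP, where 9 of 17 genes of the list rose and 1 fell. There it stood at 13.8, 16.8 and 13.9 CPM in replicates 1, 2 and 3, against 37.6, 33.2 and 35.8 CPM in Control. Single H2 genes are uncertain because they share near-identical stretches. Among macrophage markers, Cd68 fell to 11.3 ± 2.11 from 27.1 ± 1.94 CPM, and Mrc1 rose to 5.92 ± 0.577 from 2.25 ± 0.283 CPM. The Mrc1 call ended without Control replicate 2 (0.067) and with limma on FPKM + 1 (0.054). Cd14 stood at 11.7 ± 0.424 against 12.2 ± 0.489 CPM and did not pass. The lymphocyte marker Lck stood at 1.17 ± 0.507 against 1.62 ± 0.127 CPM and did not pass. Of 15 macrophage and 14 lymphocyte markers, 3 and 1 had enough counts to be tested, and of 12 fibroblast and 12 endothelial markers 4 and 3 had. Of the 3 endothelial markers tested, 0 rose and 1 fell, Eng, from 43.2 ± 2.3 to 36.2 ± 0.93 CPM. The Eng call ended in many alternatives, among them RLE factors (0.06) and DESeq2 (0.086).

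In the mesenchymal and matrix list, 4 of 22 genes rose, 13 fell and 5 did not pass (median -0.57, camera adjusted p = 0.0066, and adjusted p = 0.23 with an estimated correlation). Of the 4 fibroblast markers tested, 0 rose and 2 fell, Pdgfra from 35 ± 2.57 to 17.2 ± 1.64 CPM and Col1a1 from 2.08 ± 0.567 to 0.863 ± 0.222 CPM. The Col1a1 call ended without Control replicate 1 (0.13) or 2 (0.074) or any 1 Cu_TCPP library (0.052 to 0.11). It also ended with offsets for length and GC content (0.057) and with limma on FPKM + 0.1 (0.056). The matrix genes Thbs1 and Fn1 fell, from 597 ± 10.4 to 119 ± 2.75 CPM and from 1684 ± 67 to 760.0 ± 29.8 CPM. Of the epithelial genes, 4 of 18 genes rose, 9 fell and 5 did not pass (median -0.25, camera adjusted p = 0.045, and adjusted p = 0.29 with an estimated correlation), a call that ended with RLE factors (0.054), offsets for gene length (0.057) or length and GC content (0.08), and without Control replicate 2 or 3, any 1 Cu_TCPP library, or Au_TCPP replicate 1 or 2 (0.056 to 0.11). Jup, a junction protein, fell 2.19-fold. In autophagy and lysosome, 2 of 30 genes rose, 15 fell and 13 did not pass (median -0.27, camera adjusted p = 0.0049, and adjusted p = 0.23 with an estimated correlation), with Tfeb, a transcription factor of lysosomal genes, at 6.49 ± 0.924 against 13.3 ± 0.199 CPM. Tfeb was also low with Au_TCPP, at 4.855, 7.282 and 7.023 CPM in replicates 1, 2 and 3, although 21 of 30 genes of the list rose there. The immediate early genes had a median of -0.21 and a test direction upward, with no call (camera adjusted p = 0.95): 6 of 24 genes rose, 8 fell and 10 did not pass. Fosl1, an AP-1 subunit, rose 4.86-fold. Outside the lists, Cyp1b1 (ENSMUSG00000024087, mm10 chromosome 17, 79706953 to 79715041), a cytochrome P450, fell 34.5-fold from 53.7 ± 1.4 to 1.54 ± 0.339 CPM, with a log2 fold change of -5.11 and adjusted p = 6.7e-11. Where adjustment over the list alone changed the counts, the counts adjusted over the list alone were 6 risen and 3 fallen in copper and metallothionein, 6 risen and 8 fallen in iron handling and ferroptosis and 14 risen and 5 fallen in NRF2 targets. They were 10 risen and 3 fallen in unfolded protein response, 25 risen and 0 fallen in ribosome biogenesis and 0 risen and 0 fallen in ribosomal proteins. They were 22 risen and 1 fallen in G1/S and DNA replication, 4 risen and 1 fallen in G2/M and mitosis and 10 risen and 9 fallen in p53 targets. They were 6 risen and 10 fallen in apoptosis regulators, 6 risen and 1 fallen in pentose phosphate pathway and 9 risen and 1 fallen in sterol biosynthesis. They were 1 risen and 11 fallen in MHC class I presentation, 4 risen and 14 fallen in mesenchymal and matrix genes and 5 risen and 11 fallen in epithelial genes. They were 2 risen and 16 fallen in autophagy and lysosome, 8 risen and 9 fallen in immediate early genes and 11 risen and 2 fallen in hypoxia response. They were 5 risen and 9 fallen in glutathione metabolism. The counts of the other lists stayed as they were.

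**Figure D2:**
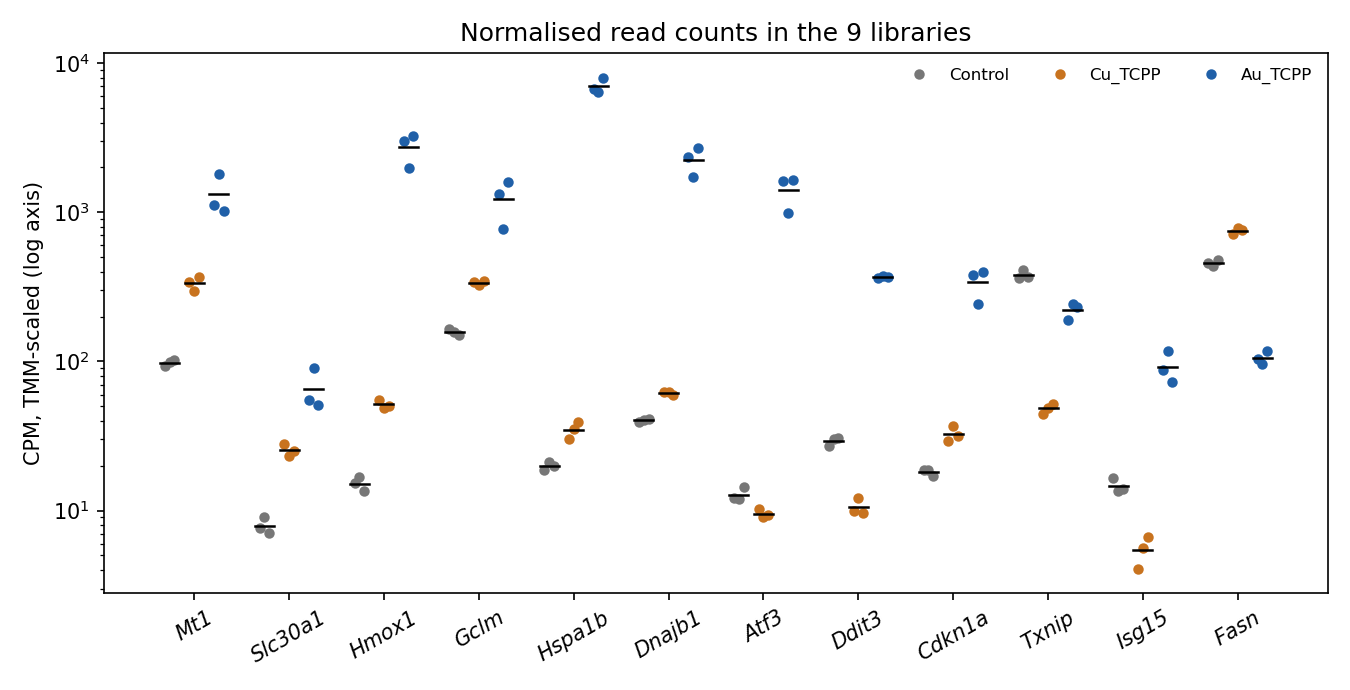
CPM on a log axis of 12 named genes in each of the 9 libraries, by group (points are libraries, black bars are means, n = 3). Hmox1 stands at 15.2 ± 1.59 CPM in Control, 51.4 ± 3.14 in Cu_TCPP and 2763 ± 675 in Au_TCPP, and Isg15 at 14.7 ± 1.61, 5.44 ± 1.27 and 92.4 ± 23 CPM.

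The comparison of Au_TCPP with Control addresses what the material that consumes GSH and acts on glucose changed in the cells. In the heat shock, immediate early and NRF2 lists 20 of 21, 21 of 24 and 24 of 29 genes rose, and 29 of 34 mitotic and 13 of 18 fatty acid synthesis genes fell. These 5 calls were lost with an estimated correlation (adjusted p = 0.089, 0.089, 0.32, 0.33 and 0.38 with an estimated correlation). Hmox1 rose 182-fold, from 15.2 ± 1.59 to 2763 ± 675 CPM, and Hspa1b, an inducible HSP70, rose from 19.9 ± 1.19 to 7047 ± 854 CPM. Fasn fell 4.33-fold, from 458 ± 19.9 to 106 ± 10.7 CPM. edgeR called 4783 genes higher and 4828 lower, of which 1891 and 2112 changed by at least 1 log2 unit. With library totals as the only scale the split was 2626 higher and 7098 lower.

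In the heat shock list, 20 of 21 genes rose, 0 fell and 1 did not pass (median 3.14, camera adjusted p = 8.2e-42, and adjusted p = 0.089 with an estimated correlation). Hspa1b (ENSMUSG00000090877, mm10 chromosome 17, 34956436 to 34959238) had a log2 fold change of 8.46 (adjusted p = 3.9e-14). Its near-identical copy Hspa1a had 5 counts over the 3 Control libraries and 159 ± 22.4 CPM in Au_TCPP, a log2 fold change of 10.65 that was 11.29 without Control replicate 3, and how reads divide between the copies is uncertain. The co-chaperone genes Dnajb1 and Dnajb4 rose 56-fold and 23.1-fold, to 2255 ± 487 and 760.2 ± 94.3 CPM. In the unfolded protein response, 17 of 22 genes rose, 2 fell and 3 did not pass (median 1.01, camera adjusted p = 1.9e-06, and adjusted p = 0.28 with an estimated correlation), with Hspa5, the main chaperone of the endoplasmic reticulum, at 8688 ± 2230 against 942 ± 9.61 CPM and Dnajb9 at 166 ± 13 against 13.3 ± 1.12 CPM. Of the ATF4 list, 19 of 27 genes rose, 3 fell and 5 did not pass (median 0.95, camera adjusted p = 1.4e-08, and adjusted p = 0.32 with an estimated correlation). Atf3 (ENSMUSG00000026628, mm10 chromosome 1, 191170296 to 191218039), a stress-induced transcription factor, rose from 12.8 ± 1.36 to 1419 ± 376 CPM, and Ppp1r15a, a phosphatase subunit that acts on eIF2, rose 34.5-fold. Ddit3, uncertain for the overlap with Mars, stood at 367 ± 5.26 against 29.4 ± 1.88 CPM (adjusted p = 3.2e-12). Of the immediate early genes, 21 of 24 genes rose, 1 fell and 2 did not pass (median 2.03, camera adjusted p = 7.7e-24, and adjusted p = 0.089 with an estimated correlation), with Jun at 835 ± 9.52 against 47.3 ± 2.89 CPM and the phosphatase gene Dusp1 at 433 ± 73.3 against 9.46 ± 1.08 CPM.

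Of the NRF2 targets, 24 of 29 genes rose, 1 fell and 4 did not pass (median 1.24, camera adjusted p = 1.1e-10, and adjusted p = 0.32 with an estimated correlation). Hmox1 (ENSMUSG00000005413, mm10 chromosome 8, 75093621 to 75100589) had a log2 fold change of 7.51 (adjusted p = 4.8e-12), and Gclm rose 7.78-fold to 1233 ± 426 CPM. In glutathione metabolism, 17 of 25 genes rose, 0 fell and 8 did not pass (median 0.55, camera adjusted p = 4.2e-05, and adjusted p = 0.23 with an estimated correlation). Gclc, the catalytic subunit of the first enzyme of GSH synthesis, rose from 34.8 ± 1.68 to 147 ± 17.1 CPM and Mgst1 rose 2.64-fold. Slc7a11 stood at 131 ± 82.2 against 35.8 ± 1.48 CPM (adjusted p = 0.011), with 137, 46.7 and 211 CPM in Au_TCPP replicates 1, 2 and 3. In the iron list, 14 of 23 genes rose, 4 fell and 5 did not pass (median 0.43, camera adjusted p = 0.00041, and adjusted p = 0.19 with an estimated correlation). The ferritin genes Fth1 and Ftl1, which have pseudogenes that can share their reads, rose 4.46-fold and 3.93-fold. Gpx4 stood at 741 ± 113 against 531 ± 19.3 CPM (adjusted p = 0.00083), a call that ended with library totals alone (0.62) and with offsets for gene length (0.078). Of the copper and metallothionein list, 12 of 19 genes rose, 4 fell and 3 did not pass (median 0.51, camera adjusted p = 0.0081, and adjusted p = 0.23 with an estimated correlation), with Mt1 at 1323 ± 432 CPM (13.5-fold), Mt2 at 38.6 ± 20.3 CPM and Slc30a1 at 65.5 ± 21.8 CPM. The cuproptosis list went both ways, with a median of 0.20, a mean of -0.04 and no call (camera adjusted p = 0.86): 6 of 14 genes rose, 4 fell and 4 did not pass.

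Of the hypoxia list, 18 of 22 genes rose, 1 fell and 3 did not pass (median 1.63, camera adjusted p = 2.3e-12, and adjusted p = 0.19 with an estimated correlation), with Vegfa, a growth factor for vessels, at 359.8 ± 32.8 against 86.3 ± 1.72 CPM. In glycolysis, 14 of 22 genes rose, 2 fell and 6 did not pass (median 0.67, camera adjusted p = 0.00044, and adjusted p = 0.27 with an estimated correlation). The glucose transporter gene Slc2a1 rose 3.31-fold and Pgk1, a phosphoglycerate kinase, 2.48-fold. The glucose-sensing list was not called (camera adjusted p = 0.98): 5 of 12 genes rose, 4 fell and 3 did not pass. Txnip fell from 382 ± 25.9 to 222 ± 27.8 CPM. Of fatty acid synthesis, 3 of 18 genes rose, 13 fell and 2 did not pass (median -0.90, camera adjusted p = 0.0029, and adjusted p = 0.38 with an estimated correlation), a median that was -0.54 with offsets for length and GC content, with Fasn (ENSMUSG00000025153, mm10 chromosome 11, 120805846 to 120824547) at a log2 fold change of -2.11 (adjusted p = 2.5e-10) and Acaca, the acetyl-CoA carboxylase, 4.29-fold lower. Of sterol biosynthesis, 0 of 24 genes rose, 9 fell and 15 did not pass (median -0.38, camera adjusted p = 0.024, and adjusted p = 0.7 with an estimated correlation). The sterol median was -0.67 without Au_TCPP replicate 1. Without Au_TCPP replicate 2 it was -0.10 and the call ended (0.18). In that library the sterol median was -1.07 against -0.02 and -0.15 in the other Au_TCPP libraries, and the fatty acid list's was -1.29 against -0.61 and -0.60. The lists of the pentose phosphate pathway (4 of 11 genes rose and 1 fell, camera adjusted p = 0.83), the TCA cycle (6 of 21 genes rose and 6 fell, camera adjusted p = 0.63, median 0.03, mean -0.14) and mitochondrially encoded genes (6 of 12 genes rose and 3 fell, camera adjusted p = 0.85) were not called. The median of the mitochondrially encoded genes was 0.28, with 0.20, 0.68 and 0.01 in Au_TCPP replicates 1, 2 and 3. It was 0.06 without replicate 2, and with offsets for length and GC content it was -0.56 and the list was called lower (0.04).

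Of 42 ribosomal protein genes, uncertain one by one, 42 rose (median 1.19, camera adjusted p = 5.1e-20, and adjusted p = 0.089 with an estimated correlation). Of nuclear OXPHOS subunits, 44 of 51 genes rose, 0 fell and 7 did not pass (median 0.64, camera adjusted p = 1.2e-06, and adjusted p = 0.23 with an estimated correlation). With offsets that remove the trend on gene length the medians of these lists were 0.96 and 0.34. In ribosome biogenesis, 16 of 28 genes rose, 7 fell and 5 did not pass (median 0.38, camera adjusted p = 0.042, and adjusted p = 0.54 with an estimated correlation), a median that was -0.04 with library totals alone. The ribosome biogenesis call ended with those totals (0.23) and without Au_TCPP replicate 3 (0.081), Control replicate 2 (0.054), Control replicate 3 (0.057), Cu_TCPP replicate 1 (0.051) or Cu_TCPP replicate 2 (0.05). Npm1, a nucleolar histone chaperone, stood at 2970 ± 166 against 1413 ± 68.4 CPM.

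In the list of G2/M and mitosis, 1 of 34 genes rose, 29 fell and 4 did not pass (median -0.89, camera adjusted p = 2.1e-08, and adjusted p = 0.33 with an estimated correlation), with Plk1, a mitotic kinase, at 31.7 ± 5.49 against 138 ± 5.1 CPM and Ccnb1, cyclin B1, at 66 ± 2.88 against 193 ± 6.04 CPM. In DNA repair, 4 of 30 genes rose, 18 fell and 8 did not pass (median -0.45, camera adjusted p = 0.007, and adjusted p = 0.33 with an estimated correlation). The median was -0.20 with offsets for gene length and -0.13 with offsets for length and GC content. Brca2, which serves homologous recombination, fell 3.65-fold. The G1/S list went both ways and was not called (camera adjusted p = 0.86, median 0.01, mean -0.02): 15 of 35 genes rose, 13 fell and 7 did not pass. Pcna, the sliding clamp of replication, rose 2.64-fold, while Pole, a polymerase subunit, fell 3.46-fold. Of the p53 targets, 13 of 24 genes rose, 6 fell and 5 did not pass (median 0.65, camera adjusted p = 0.0006, and adjusted p = 0.089 with an estimated correlation), with Cdkn1a at 339 ± 84.1 against 18.2 ± 0.923 CPM. Apoptosis regulators were not called (camera adjusted p = 0.92): 10 of 27 genes rose, 11 fell and 6 did not pass. Mcl1 rose 1.8-fold and Bcl2 fell 3-fold; both encode proteins that restrain apoptosis.

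In the interferon-response list, 27 of 30 genes rose, 0 fell and 3 did not pass (median 1.82, camera adjusted p = 7.3e-05, and adjusted p = 0.44 with an estimated correlation). The per-library medians were 1.45, 2.46 and 1.04 in Au_TCPP replicates 1, 2 and 3, and the median of the comparison was 1.21 without replicate 2. Isg15 (ENSMUSG00000035692, mm10 chromosome 4, 156199424 to 156200818), a ubiquitin-like antiviral protein, rose 6.3-fold to 92.4 ± 23 CPM. All 3 macrophage markers tested rose, Cd68 to 61.3 ± 12.1 from 27.1 ± 1.94 CPM, Cd14 to 20.5 ± 1.91 from 12.2 ± 0.489 CPM and Mrc1 to 6.1 ± 3.73 from 2.25 ± 0.283 CPM. Mrc1 stood at 8.66, 1.82 and 7.81 CPM in Au_TCPP replicates 1, 2 and 3, against 2.5, 1.94 and 2.3 CPM in Control. Au_TCPP replicate 2 thus lay below every Control library. The Mrc1 call ended with limma on FPKM + 0.1 (0.061). The lymphocyte marker Lck rose to 2.91 ± 1.05 from 1.62 ± 0.127 CPM (adjusted p = 0.04). That call ended in 11 alternatives, among them DESeq2 (0.073), library totals (0.3) and offsets for gene length (0.067), and on leaving out any 1 Control library (0.078 to 0.12), Au_TCPP replicate 2 (0.069), Au_TCPP replicate 3 (log2 0.54, 0.21) or Cu_TCPP replicate 3 (0.051). Of the fibroblast markers tested, 1 of 4 rose and 2 fell, and of the endothelial markers 0 of 3 rose and 2 fell. With offsets for length and GC content the fibroblast markers S100a4 and Pdgfra changed direction and the call of the endothelial marker Eng ended (0.71). The list of MHC class I presentation (9 of 17 genes rose and 1 fell, camera adjusted p = 0.13) was not called but passed without Au_TCPP replicate 3 (0.023). The list of chemokines and NF-kB targets (11 of 30 genes rose and 12 fell, camera adjusted p = 0.85) was not called. Csf2, a growth factor for myeloid cells, rose 13.3-fold and Cx3cl1 fell 4.78-fold. In autophagy and lysosome, 21 of 30 genes rose, 3 fell and 6 did not pass (median 0.69, camera adjusted p = 7.6e-05, and adjusted p = 0.13 with an estimated correlation), with Ctsd, a lysosomal protease, at 207 ± 16.3 against 86.5 ± 2.68 CPM. Epithelial (10 of 18 genes rose and 6 fell, camera adjusted p = 0.28) and mesenchymal genes (10 of 22 genes rose and 9 fell, camera adjusted p = 0.96) were not called, although the epithelial list passed with offsets for length and GC content (0.026). Thbs1 fell 7.09-fold. Where adjustment over the list alone changed the counts, the counts adjusted over the list alone were 13 risen and 4 fallen in copper and metallothionein, 15 risen and 14 fallen in G1/S and DNA replication and 11 risen and 9 fallen in mesenchymal and matrix genes. They were 22 risen and 1 fallen in immediate early genes. The counts of the other lists stayed as they were.

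**Figure D3:**
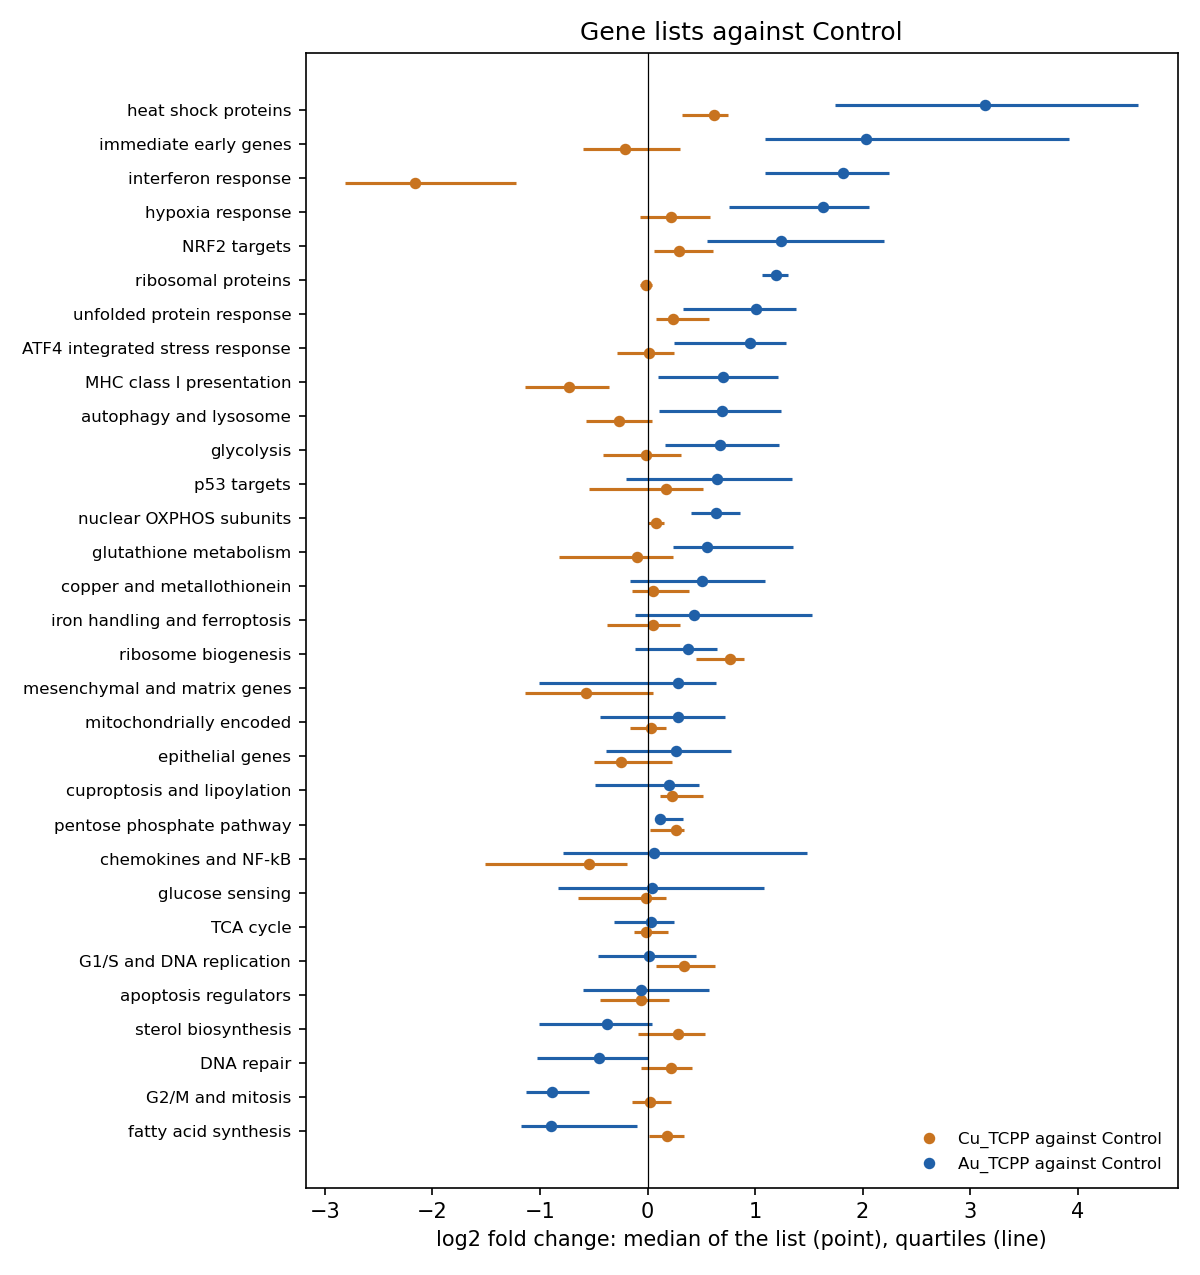
Median log2 fold change (points) with lower and upper quartiles (bars) of the genes of each of 31 lists, for Cu_TCPP and Au_TCPP against Control. The interferon-response list lies at -2.16 with Cu_TCPP and 1.82 with Au_TCPP, and the heat shock list at 0.62 and 3.14.

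The comparison of Au_TCPP with Cu_TCPP addresses what the material with gold changed beyond the one without, and it tests the difference between the effects of the 2 materials directly. In the interferon-response and heat shock lists 29 of 30 and 20 of 21 genes were higher with Au_TCPP, and 30 of 34 mitotic and 14 of 18 fatty acid synthesis genes were lower. These 4 calls were lost with an estimated correlation (adjusted p = 0.23, 0.096, 0.29 and 0.29 with an estimated correlation). Isg15 rose from 5.44 ± 1.27 CPM in Cu_TCPP to 92.4 ± 23 CPM in Au_TCPP, and Fasn fell from 754 ± 32.8 to 106 ± 10.7 CPM. edgeR called 4814 genes higher and 4362 lower, of which 2054 and 1675 differed by at least 1 log2 unit. With library totals as the only scale the split was 2830 higher and 6526 lower.

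The interferon-response list had the highest median of the 31 lists in this comparison: 29 of 30 genes rose, 0 fell and 1 did not pass (median 4.13, camera adjusted p = 2.5e-14, and adjusted p = 0.23 with an estimated correlation). Isg15 had a log2 fold change of 4.08 (adjusted p = 1.2e-09) and Ifit1 one of 4.87, at 26.6 ± 1.91 against 0.91 ± 0.484 CPM. Ifih1, a cytosolic sensor of double-stranded RNA, rose 3.4-fold. Of MHC class I presentation, 14 of 17 genes rose, 1 fell and 2 did not pass (median 1.18, camera adjusted p = 0.0013, and adjusted p = 0.44 with an estimated correlation), with B2m, the light chain of class I molecules, at 1082 ± 236 against 313 ± 29.1 CPM. Of chemokines and NF-kB targets, 17 of 30 genes rose, 7 fell and 6 did not pass (median 0.41, camera adjusted p = 0.0025, and adjusted p = 0.089 with an estimated correlation), with Ccl5 7-fold and Il1a 4.22-fold higher. Cd68 was 5.41-fold and Cd14 1.76-fold higher, Lck stood at 2.91 ± 1.05 against 1.17 ± 0.507 CPM (adjusted p = 0.0045), and Mrc1 at 6.1 ± 3.73 against 5.92 ± 0.577 CPM did not pass. Of the fibroblast markers tested, 2 of 4 rose and 0 fell, and of the endothelial markers 0 of 3 rose and 0 fell.

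In the heat shock list, 20 of 21 genes rose, 1 fell and 0 did not pass (median 2.63, camera adjusted p = 3.4e-33, and adjusted p = 0.096 with an estimated correlation). Dnajb1 (ENSMUSG00000005483, mm10 chromosome 8, 83608193 to 83612653) had a log2 fold change of 5.19 (adjusted p = 4.7e-12). Of the immediate early genes, 21 of 24 genes rose, 0 fell and 3 did not pass (median 2.09, camera adjusted p = 5.8e-25, and adjusted p = 0.089 with an estimated correlation), and Fos, an AP-1 subunit, rose 42.1-fold. Of the ATF4 list, 19 of 27 genes rose, 3 fell and 5 did not pass (median 1.05, camera adjusted p = 1.4e-09, and adjusted p = 0.29 with an estimated correlation), with Atf3 149-fold higher. In the unfolded protein response, 15 of 22 genes rose, 3 fell and 4 did not pass (median 0.60, camera adjusted p = 0.001, and adjusted p = 0.4 with an estimated correlation), and Xbp1, one of its transcription factors, rose 2.09-fold. Of the p53 targets, 13 of 24 genes rose, 5 fell and 6 did not pass (median 0.46, camera adjusted p = 0.00098, and adjusted p = 0.089 with an estimated correlation), a median that was 0.23 with offsets for gene length, with Btg2, an antiproliferative gene, at 72.2 ± 9.56 against 2.73 ± 0.425 CPM. Apoptosis regulators were not called (13 of 27 genes rose and 11 fell, camera adjusted p = 0.77). Bcl2l11, which fell with Cu_TCPP, was 2.02-fold higher than there but near Control. It stood at 90.4, 96.9 and 96.3 CPM in Au_TCPP replicates 1, 2 and 3 and at 88.3, 91.2 and 98.4 CPM in Control. Bcl2l1, which encodes the survival protein BCL-XL, fell 1.91-fold.

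Of the NRF2 targets, 22 of 29 genes rose, 1 fell and 6 did not pass (median 1.14, camera adjusted p = 1.1e-08, and adjusted p = 0.37 with an estimated correlation), with Hmox1 53.7-fold higher and Sqstm1, an autophagy receptor, at 3890 ± 1030 against 488 ± 35.7 CPM. Aldh3a1, which fell with Cu_TCPP, stood at 109 ± 30.5 against 4.14 ± 0.475 CPM. In glutathione metabolism, 20 of 25 genes rose, 0 fell and 5 did not pass (median 1.33, camera adjusted p = 5.9e-08, and adjusted p = 0.17 with an estimated correlation), with Gclm (ENSMUSG00000028124, mm10 chromosome 3, 122245557 to 122270732) at a log2 fold change of 1.87 (adjusted p = 6.4e-06) and Mgst1 5.9-fold higher. Slc7a11 rose from 42.2 ± 3.58 to 131 ± 82.2 CPM (adjusted p = 0.02), a call that ended without Cu_TCPP replicate 1 (0.055), 2 (0.059) or 3 (0.058), with no filter (0.063) and in a fit of these 6 libraries (0.055). Its log2 fold change of 1.64 was 1.07 without Au_TCPP replicate 3. In the iron list, 13 of 23 genes rose, 3 fell and 7 did not pass (median 0.31, camera adjusted p = 0.00017, and adjusted p = 0.17 with an estimated correlation), a median that was -0.07 with library totals alone. Gpx4 rose 2.51-fold and Sat1, a polyamine acetyltransferase, 5.29-fold. Of the copper and metallothionein list, 10 of 19 genes rose, 3 fell and 6 did not pass (median 0.40, camera adjusted p = 0.036, and adjusted p = 0.29 with an estimated correlation), a call that ended with library totals alone (0.052) and with offsets for gene length (0.052) or length and GC content (0.057). Mt1 was 3.95-fold higher. The cuproptosis list was not called (3 of 14 genes rose and 7 fell, camera adjusted p = 0.27).

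Of the hypoxia list, 18 of 22 genes rose, 2 fell and 2 did not pass (median 1.17, camera adjusted p = 2.5e-09, and adjusted p = 0.23 with an estimated correlation). Of glycolysis, 17 of 22 genes rose, 1 fell and 4 did not pass (median 0.62, camera adjusted p = 0.00023, and adjusted p = 0.24 with an estimated correlation). Vegfa was 4.42-fold and Aldoa, an aldolase, 2.68-fold higher. Txnip, lower than Control in both treatments, rose from 48.4 ± 3.86 to 222 ± 27.8 CPM, while its list was not called (7 of 12 genes rose and 3 fell, camera adjusted p = 0.26). Of fatty acid synthesis, 2 of 18 genes rose, 14 fell and 2 did not pass (median -0.85, camera adjusted p = 0.00019, and adjusted p = 0.29 with an estimated correlation). Of sterol biosynthesis, 2 of 24 genes rose, 16 fell and 6 did not pass (median -0.73, camera adjusted p = 0.00096, and adjusted p = 0.52 with an estimated correlation). Fasn was 7.14-fold lower. The pentose phosphate (3 of 11 genes rose and 1 fell, camera adjusted p = 0.68), TCA cycle (5 of 21 genes rose and 4 fell, camera adjusted p = 0.67, median 0.02, mean -0.08) and mitochondrially encoded lists (5 of 12 genes rose and 2 fell, camera adjusted p = 0.88) were not called. Of nuclear OXPHOS subunits, 40 of 51 genes rose, 0 fell and 11 did not pass (median 0.55, camera adjusted p = 4.2e-05, and adjusted p = 0.24 with an estimated correlation), a call that ended with offsets for gene length (median 0.26, adjusted p = 0.081) or length and GC content (median 0.14, adjusted p = 0.11). Of 42 ribosomal protein genes, 41 rose (median 1.17, camera adjusted p = 3.2e-21, and adjusted p = 0.089 with an estimated correlation).

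In the list of G2/M and mitosis, 1 of 34 genes rose, 30 fell and 3 did not pass (median -0.81, camera adjusted p = 8.8e-10, and adjusted p = 0.29 with an estimated correlation), and Espl1, which encodes separase, fell 7.54-fold from 167 ± 1.48 to 22.1 ± 1.67 CPM. Of the G1/S list, 6 of 35 genes rose, 20 fell and 9 did not pass (median -0.42, camera adjusted p = 0.018, and adjusted p = 0.54 with an estimated correlation), with Rrm2, a subunit of ribonucleotide reductase, at 65.4 ± 17.8 against 229.5 ± 12 CPM. In DNA repair, 4 of 30 genes rose, 21 fell and 5 did not pass (median -0.72, camera adjusted p = 6.4e-05, and adjusted p = 0.23 with an estimated correlation), with Exo1 2.28-fold lower. In ribosome biogenesis, 6 of 28 genes rose, 17 fell and 5 did not pass (median -0.32, camera adjusted p = 0.017, and adjusted p = 0.48 with an estimated correlation), a median that was -0.51 with offsets for gene length. Polr1a, the large subunit of RNA polymerase I, fell 2.26-fold. In autophagy and lysosome, 24 of 30 genes rose, 1 fell and 5 did not pass (median 0.77, camera adjusted p = 1.6e-08, and adjusted p = 0.089 with an estimated correlation), with Gla, a lysosomal galactosidase, at 60.9 ± 6.31 against 15.6 ± 0.474 CPM. Of the epithelial genes, 11 of 18 genes rose, 4 fell and 3 did not pass (median 0.50, camera adjusted p = 0.026, and adjusted p = 0.24 with an estimated correlation), a call that ended with library totals alone (0.11). Krt19, a keratin, was 2.52-fold higher. The mesenchymal list (13 of 22 genes rose and 5 fell, camera adjusted p = 0.11) was not called but passed without Au_TCPP replicate 2 (0.046) and with offsets for length and GC content (0.0073). Mmp9, a gelatinase, rose 5.78-fold and Ctgf, a matrix-associated growth factor, fell 8.65-fold. Control lay between the materials for both, with Mmp9 at 30.6, 28.6 and 33.8 CPM and Ctgf at 40.8, 38.9 and 39.6 CPM. Where adjustment over the list alone changed the counts, the counts adjusted over the list alone were 1 risen and 31 fallen in G2/M and mitosis, 2 risen and 1 fallen in pentose phosphate pathway and 5 risen and 4 fallen in mitochondrially encoded. They were 2 risen and 15 fallen in fatty acid synthesis, 13 risen and 6 fallen in mesenchymal and matrix genes and 12 risen and 5 fallen in epithelial genes. The counts of the other lists stayed as they were.

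The responses to the 2 materials were also set side by side across genes. Both comparisons use the same Control libraries, which alone makes fold changes correlate. The values were therefore set beside 20 simulations, in which all 9 libraries were drawn anew at the mean levels of Control. The Pearson correlation of the log2 fold changes over the 13915 genes was 0.318, and the simulated one 0.495 (range 0.47 to 0.531). Simulated fold changes hold noise alone, so the shared controls set their correlation. That the measured correlation lies below it therefore does not tell how far the responses agree. The covariance was 0.231 against a simulated 0.0281, a difference of 0.203. Among called genes, 1485 rose with both materials, against 919 for independent lists, and 1639 fell with both, against 1021. In the simulations the means were 0.1 and 0 genes, with at most 1 in total. The simulated groups hold no changed genes, so almost no gene could be called in them. Their counts therefore do not show how much overlap the shared controls give among called genes. Another 591 rose with Cu_TCPP and fell with Au_TCPP (927 for independent lists), and 537 fell with Cu_TCPP and rose with Au_TCPP (1012). The count of 537 was 354, 334 and 332 without Control replicates 1, 2 and 3 (705, 657 and 683 for independent lists). The 3 controls cannot be split into parts of 2 libraries or more, so part of the excess can come from the shared controls.

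The authors' deposited table also holds fold changes and adjusted p-values for the same comparisons, from a test not given in the sources used here. In the authors' deposited table, 6560 genes are past 0.05 for Cu_TCPP against Control, 9045 for Au_TCPP against Control and 8230 for Au_TCPP against Cu_TCPP. Of the edgeR calls, 5416, 8678 and 7897 are also past 0.05 in the authors' deposited table.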

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

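The tests of gene length, of the interferon genes, of Au_TCPP replicate 2 and of other splits of the libraries were all chosen or given their bounds after the result was seen, while the test of Au_TCPP against Cu_TCPP was planned. Genes and lists are given here because the materials moved them in opposite directions and edgeR or camera called the difference. There were 537 genes that fell with Cu_TCPP and rose with Au_TCPP, and 591 that rose with Cu_TCPP and fell with Au_TCPP. Both counts lie below those for independent lists (1012 and 927), so opposite calls were fewer than independence gives. Each gene was called in the test of the difference. Opposite calls against the same Control make that nearly certain, so it adds no support. The 537 were 354, 334 and 332 without Control replicates 1, 2 and 3. Among lists, DNA repair differed with a median of -0.72 in Au_TCPP against Cu_TCPP (-0.56 with length offsets, adjusted p = 6.4e-05, and 0.23 with an estimated correlation), autophagy and lysosome with 0.77 (adjusted p = 1.6e-08, and 0.089 with an estimated correlation), and interferon response with 4.13 (adjusted p = 2.5e-14, and 0.23 with an estimated correlation). The DNA repair median in Au_TCPP against Control, -0.45, was -0.20 with length offsets and -0.13 with length and GC offsets.

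Interferon-response genes were lower with Cu_TCPP and higher with Au_TCPP (adjusted p = 0.23 and 0.44 with an estimated correlation), and offsets for length and GC left the median of Au_TCPP against Cu_TCPP at 3.93, which argues against those trends as the whole cause. Of 29 macrophage and lymphocyte markers, the 25 under 1 CPM in Control were higher by 0.459 CPM in sum with Au_TCPP, while the 30 interferon genes were higher by 1190, and the macrophage genes Lyz2, Tyrobp and C1qa stood at 0.2, 0 and 0 CPM with Au_TCPP. These values argue against RNA from such cells, although the other 4 markers, which Control cells express, rose: Cd68 to 61.3, Cd14 to 20.5, Mrc1 to 6.09 and Lck to 2.9 CPM, from 27.1, 12.2, 2.25 and 1.62. In Au_TCPP replicate 2, however, Mrc1 stood at 1.82 CPM, below every Control library. The highest adjusted p of the list over the 3 comparisons with any 1 library left out was 5.5e-05, so no single library carries the call with the preset correlation, a call lost with an estimated correlation. An effect of the materials themselves stays open and was not tested apart from the comparisons.

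Shorter genes were higher and longer genes lower with Au_TCPP. Without ribosomal protein, respiratory chain and chaperone genes the rank correlation was -0.281 over 13571 genes, which argues against a few short families. In a joint model of ranks over 11552 protein-coding genes, the coefficient of exonic length was -0.403 (95% interval -0.424 to -0.382). That of transcript GC content was -0.357 (-0.373 to -0.34), nearly as large. Mean level had 0.237 (0.221 to 0.253) and genomic span -0.0898 (-0.111 to -0.0687). The intervals treat genes as independent, which they are not. The Au_TCPP values argue against span and against GC content as the whole cause, while fold changes fell with GC content as well as with length. In the same model for Cu_TCPP against Control, exonic length had -0.0474, genomic span -0.113, GC content -0.169 and mean level 0.282. Fold changes with Cu_TCPP thus also went with GC content and mean level, and the cause was not tested. RNA integrity or fragment size cannot be told apart from the treatment, since the weakest of the Au_TCPP libraries stood at -0.248 and the other groups between -0.138 and 0.134, so quality and group would coincide. Other shares of the counts differed by group too, though none measures integrity. In Control, Cu_TCPP and Au_TCPP, rRNA took 0.0691, 0.0727 and 0.142%, pseudogenes 1.98, 1.95 and 2.75%, and lincRNA 0.649, 0.417 and 0.316% (means, n = 3). A change of transcript stability or synthesis with Au_TCPP stays open as well and was not tested.

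Au_TCPP replicate 2 stood apart from the other Au_TCPP libraries. Its mitochondrial share of 2.367% lies above that of the other 8 libraries, which argues against RNA of the other groups as the whole cause, although 69.3% of 1308 risen and 66.7% of 1287 fallen genes lay toward Control in it. The extra mitochondrial share shifts every other gene by -0.0176 on the log2 scale, against a difference of -0.99 in the sterol list, which argues against reads taken by mitochondrial genes. No biological explanation was tested, since the design gives none within a group.

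Other splits of the 6 libraries of each comparison are too few for a share under 0.05. Of the 10 splits, 1 gave as many calls in each comparison, the real one, with 7381, 9214 and 8396 genes in fits of 6 libraries. The highest of the others was 0 in each by edgeR, with 277, 93 and 101 genes at an unadjusted p under 0.05, and no other tool was run on the splits.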

How the results depend on the processing

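Offsets for gene length, with and without GC content, protein-coding genes alone, leaving out the most counted genes, list tests with library totals alone and counts of genes called with both materials without 1 Cu_TCPP or Au_TCPP library were chosen after the result was seen, and the other alternatives were planned. With a log2 fold change of at least 1 the counts were 1146 (217 higher, 929 lower), 4003 (1891 and 2112) and 3729 (2054 and 1675) for Cu_TCPP against Control, Au_TCPP against Control and Au_TCPP against Cu_TCPP, by construction of the stricter threshold. With library totals alone, 2626 and 2830 genes were higher in the comparisons of Au_TCPP with Control and with Cu_TCPP, in place of 4783 and 4814, because the median of all genes moved. The other counts stayed within 1.5 times of the reported ones, with leave-one-out totals of 4226 to 7179, 8859 to 10109 and 8521 to 9622. camera called 58 of 93 list tests with the preset correlation and 0 with an estimated correlation, where 19 had an unadjusted p under 0.05. The correlation of the responses was 0.293 with at least 5 CPM and 0.327 to 0.339 without a Control replicate, and the covariance 0.143, 0.253 to 0.269 and, with length offsets, 0.229, and the cause was not tested. Without any 1 library, 1063 to 2004 genes rose and 1213 to 2073 fell with both materials, 401 to 886 rose with Cu_TCPP and fell with Au_TCPP, and 332 to 664 did the opposite. Replicate numbers did not pair the libraries (correlations of same-numbered libraries -0.0846 to 0.0897), and a replicate block gave 5508, 9505 and 9059 calls, with the sterol list called for Cu_TCPP against Control (0.037) and no other list call changed. Apart from the estimated correlation, 66 of the 93 list tests kept direction and side of the threshold, 7 calls ended and 7 tests gained a call in at least 1 alternative. In camera's test no called list reversed, and 13 list tests that were not called changed direction, of which the mitochondrially encoded genes were then called lower in Au_TCPP against Control with length and GC offsets (0.04). The medians of 3 called lists changed sign, that of glucose sensing in Cu_TCPP against Control (-0.01, and 0.02 with RLE factors), of ribosome biogenesis in Au_TCPP against Control (0.38, and -0.04 with library totals) and of iron handling in Au_TCPP against Cu_TCPP (0.31, and -0.07 with library totals). Of the 417 results of named genes, 386 kept direction and side of the threshold in every alternative run, 26 lost the call in at least 1 of them, 2 gained it and 9 reversed, and 3 that were not called changed direction without a call, with overlap between these groups.

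The reversed genes, none called in the reversed direction, were as follows, and the cause was not tested. In Au_TCPP against Control, Pdgfra went from -0.32 to 0.08 with length offsets and 0.15 with length and GC offsets. Prps1 went from 0.35 to -0.08 with library totals and -0.15 with length and GC offsets, and Taldo1 from 0.39 to -0.04 with library totals. S100a4 went from 0.40 to -0.02 with library totals, -0.13 with length offsets and -0.20 with length and GC offsets, and mt-Cytb from 0.67 to -0.19 with length and GC offsets. In Au_TCPP against Cu_TCPP, Pgls went from 0.33 to -0.05 with library totals. With length and GC offsets S100a4 went from 0.57 to -0.01, mt-Nd2 from 0.59 to -0.14 and mt-Nd4 from 0.52 to -0.15.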

Other observations

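The lists of proteasome subunits, CCT chaperonin, mitochondrial ribosomal proteins, circadian genes and zinc transporters were chosen after the result was seen, and so were the genes named here. Their camera p-values were adjusted over 15 tests of their own, apart from the 93 of the fixed lists. Offsets for gene length were not run for these lists. In Au_TCPP against Control, all genes tested of up to 500 nt had a median of 0.86, and those over 8000 nt one of -0.45. How far gene length accounts for the medians of these lists with Au_TCPP, against Control or Cu_TCPP, was therefore not tested. Proteasome subunits, which form the main protease of the cytosol, rose in 23 of 31 genes with Cu_TCPP (median 0.40, camera adjusted p = 2.4e-06, and adjusted p = 0.47 with an estimated correlation). With Au_TCPP all 31 rose (median 1.22, camera adjusted p = 1.1e-12, and adjusted p = 0.47 with an estimated correlation), and 29 were higher than with Cu_TCPP (median 0.78, camera adjusted p = 2.4e-06, and adjusted p = 0.47 with an estimated correlation). Psma1, a core subunit, stood at 149 ± 2.29 CPM in Control, 197 ± 3.27 in Cu_TCPP and 339.9 ± 63.5 in Au_TCPP. The CCT chaperonin, which folds actin and tubulin, rose in 8 of 8 genes with Au_TCPP (median 1.00, camera adjusted p = 0.00063, and adjusted p = 0.47 with an estimated correlation) and in 6 with Cu_TCPP (camera adjusted p = 0.054). All 8 were higher with Au_TCPP than with Cu_TCPP (median 0.69, camera adjusted p = 0.011, and adjusted p = 0.47 with an estimated correlation). Mitochondrial ribosomal proteins rose in 18 of 32 genes with Cu_TCPP (median 0.28, camera adjusted p = 0.0012, and adjusted p = 0.13 with an estimated correlation) and in 20 with Au_TCPP (median 0.31, camera adjusted p = 0.0077, and adjusted p = 0.14 with an estimated correlation). Between the materials 13 were higher and 5 lower with Au_TCPP (camera adjusted p = 0.31). Zinc transporters rose in 7 and fell in 1 of 15 genes with Cu_TCPP (median 0.27, camera adjusted p = 0.0077, and adjusted p = 0.24 with an estimated correlation), with Slc39a10, a zinc importer, at 106 ± 4.3 against 40 ± 3.69 CPM. That list was not called in Au_TCPP against Control, where 6 rose and 5 fell (median 0.12, camera adjusted p = 0.81), or against Cu_TCPP, where 4 rose and 6 fell (median -0.18, camera adjusted p = 0.26). The circadian list was not called in any comparison (camera adjusted p = 0.5, 0.26 and 0.12).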
